A study of Oryza sativa with 8 samples.

How the data were processed

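Transcripts were measured by RNA sequencing in 14-day-old rice seedlings of wild-type, called NIP in the series, and of an SDG708 RNAi line. SDG708 encodes a SET-domain protein of the family that methylates histone H3. Seedlings spent 7 days on plates and 7 days in liquid medium with 10 h of light at 30 °C and 14 h of dark at 28 °C, and the treated plants then stood in 20% polyethylene glycol (PEG) 8000 for 3 h. PEG of this size lowers the water potential of the medium without entering the cells, and so withdraws water from the roots. Polyadenylated RNA was selected and made into stranded libraries, per the labels' protocols. The 3 groups were untreated wild-type (WT_control, n = 3), wild-type under PEG (WT_PEG, n = 2) and the RNAi line under PEG (708RNAi_PEG, n = 3). Groups and replicate numbers were taken from the sample titles. No untreated RNAi sample was analysed here, so a difference between the RNAi line and wild-type under PEG cannot be divided into a part that depends on PEG and a part that does not.

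The deposited table holds FPKM values per gene and library, the authors' group means, and the authors' log2 fold change and p-value for 2 comparisons. FastQC, cutadapt, HISAT2, SAMtools, featureCounts, DESeq2 and deepTools are named in the submitters' processing notes, without a role or version. The genome build and annotation are not given in the sources used here, and neither is whether reads were counted by strand, so a gene and an overlapping antisense gene may share reads. Whether the authors' deposited p-value is adjusted for multiple testing is not given in the sources used here either. The authors' deposited log2 fold changes lay close to the log2 ratio of mean FPKM, with a median absolute difference of 0.0004 for the PEG response and 0.0016 for the RNAi comparison.

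The FPKM values step in multiples of what 1 read is worth, and whole reads were recovered for 34119 of 34119 rows within a tolerance of 0.03 reads. Recovered reads per library ran from 30818621 to 49708810. The reads in the rows came to 87.0% to 103.3% of the denominators behind the FPKM values. A denominator below the number of reads is no library total. Divided by a median-of-ratios size factor computed from the recovered reads, the denominators lay between 37.3 and 38.9 megareads in all 8 libraries. The mean share was 88.6% ± 2.4 in WT_control (SD, n = 3), 97.8% ± 0.7 in WT_PEG (SD, n = 2) and 102.4% ± 1.0 in 708RNAi_PEG (SD, n = 3), so that scaling to total reads instead moves the treated libraries down against the untreated ones. Gene lengths recovered from the steps had a median of 2805 bp and, for 70 of 86 loci with a named counterpart, lay within 10% of the whole gene span in the reference, introns included. Comparisons of FPKM between genes therefore depend on intron length, while the ratio of FPKM of 1 gene between libraries does not. A longer span lowers FPKM, so the filter and the fold changes of log2(FPKM + 1) used below do depend on it.

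Locus identifiers are in the MSU form, and 0 of them occur in the reference gene table given (assembly ASM3414082v1), which was used for names only. Before the data were examined, 15 gene lists with 123 loci were fixed from memory by locus identifier. For 86 loci the name was found in the reference on the same chromosome, and 84 of these kept the order along the chromosome. The remaining pair, PP2C loci, were out of order and are counted without being named. The reference holds no such name for 36 loci, whose names rest on the list alone, and 1 contradicted locus was dropped. The names of NCED1, NCED2, NCED4, NCED5, SNAC1, NAC10, bZIP46, bZIP72, bZIP12, RAB16A, WSI18, GOLS1, GOLS2, PRODH, TPS1, CATC, RCC3, MADS51, PRR59, SDG724, SDG725 and all 12 leaf photosynthesis genes belong to these. Rows for 2 of the listed loci, SDG708 among them, were not analysed here, so the knockdown itself was not checked in these libraries. Lists chosen by keyword were not used, because the tables given hold no product descriptions. A list of 12 seed genes was written after the values were seen.

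Genes with an FPKM of at least 1 in at least 2 libraries were kept, which left 20943. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a variance trend), with all 3 groups in one model, 5 residual degrees of freedom, two-sided tests and a Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of low genes, and folds printed in words are ratios of mean FPKM. Gene lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison. The overlap of the PEG response with the RNAi comparison was set beside independent lists and beside 100 simulated data sets without effects that share the WT_PEG libraries. The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the tested genes of abscisic acid (ABA) synthesis and catabolism, the 8 largest rises and falls in each of the first 2 comparisons, and up to 4 members of each list with the smallest p. The largest rises and falls were taken from called genes with non-overlapping groups, a mean FPKM of at least 5 in the higher group and a name in the reference. Because only listed loci could be matched to names, those are the largest among the lists, not among all genes. Up to 2 loci without a name are given per direction. Outside the rule, RAB16A, DREB1C, SAPK7 and TPS1 are given for the PEG response, and WSI18, RBCS2, RBCS3 and RBCS4 for the RNAi comparison. Those values are not among the named-gene results checked under the alternatives.

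In data simulated from the real read means, gene lengths and denominators with a 5% variation beyond counting, 200 genes were changed in each of 20 draws. For the PEG response, 15% of 952 genes changed 1.2-fold, 89.5% of 964 genes changed 1.5-fold and 99% of 977 genes changed 2-fold were called. For the RNAi comparison under PEG the shares were 16.4% of 962, 89.9% of 970 and 99.4% of 972. Unchanged genes made up a mean of 7.9% of the calls for the PEG response and 7.7% for the RNAi comparison, above the nominal 5%. The 200 changed genes of a draw are far fewer than the genes called in the real data. The cutoff of an adjusted p depends on the number of changed genes. Neither the shares of changed genes called nor the share of unchanged genes among calls carries over to the real counts.

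Alternatives changed the pseudocount, the filter, the scaling, the variance trend, the weights, the groups in the model and the replicates, added the replicate number as a block, and used the authors' deposited p-values. Added after seeing the data were limma-voom on the recovered reads, scaling to total recovered reads, WT_control replicates 1 and 2 averaged as 1 replicate, and, for the overlap, a different WT_PEG library in each comparison. Numerical work outside R used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.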

Results

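Gene expression was measured in 8 libraries from rice seedlings, 3 of untreated wild-type, 2 of wild-type after 3 h in 20% PEG and 3 of the SDG708 RNAi line after the same treatment. The table gave FPKM for 34119 loci, of which 302 were at 0 in every library and 20943 passed the filter. Recovered reads numbered 34197101, 35174895 and 37262837 in the untreated wild-type libraries, 36371459 and 34393100 in the wild-type PEG libraries, and 39320726, 30818621 and 49708810 in the RNAi libraries. At the median gene length 1 read was worth between 0.00741 and 0.0117 FPKM. The labels do not say that replicates came from separate plants or cultures, so every p-value measures the spread between these libraries, which may be technical. Untreated wild-type replicates 1 and 2 differed by 0.9% beyond counting noise, against 8.0% and 8.4% from replicate 3. Their mean chi-square per gene of 2.21 still exceeded counting noise, and they were counted separately.

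The first comparison asked which transcripts differed between wild-type seedlings under PEG dehydration and untreated ones. The sample details used here give no mock transfer or harvest hour for the untreated seedlings, so differences in these cannot be separated from PEG. Transcripts of late embryogenesis abundant (LEA) proteins and dehydrins, which accumulate in drying tissue, rose in 10 of 10 tested genes. LEA3-1 (LOC_Os05g46480) rose from 2.41 ± 0.77 FPKM (SD, n = 3) to 1338 ± 33.4 FPKM (SD, n = 2), and RAB16A (LOC_Os11g26790) from 4.3 ± 1.21 to 1776 ± 11.7 FPKM. RAB16B rose 678-fold, LEA3-2 671-fold, RAB16C 169-fold and RAB16D 67.5-fold in mean FPKM, although each of these had under 1 FPKM in untreated seedlings. The RAB16 genes lie side by side as similar copies, and reads may be divided uncertainly among them. The list was higher by camera (adjusted p = 2.4e-07), and its adjusted p was 0.13 with an estimated correlation.

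Genes of ABA synthesis went both ways under PEG. Of the 6 tested genes 4 rose and 2 fell. NCED3 (LOC_Os03g44380), NCED4 (LOC_Os07g05940) and NCED5 (LOC_Os12g42280), epoxycarotenoid dioxygenases of the step that commits carotenoids to ABA, rose 13.4-fold, 111-fold and 8.27-fold. NCED4 went from 1.32 ± 0.107 FPKM (SD, n = 3) to 146 ± 2.11 FPKM (SD, n = 2), a log2 fold change of 5.99 ± 0.05 (SE, limma adjusted p = 7.7e-12). ZEP1, the zeaxanthin epoxidase, rose from 22.7 ± 0.442 to 31.6 ± 0.408 FPKM. NCED1 (LOC_Os02g47510) fell from 256 ± 17.9 to 128 ± 6.18 FPKM, and NCED2 (LOC_Os12g24800) from 4.91 ± 0.375 to 0.243 ± 0.0602 FPKM. The list as a whole did not pass camera (adjusted p = 0.22). All 3 ABA hydroxylase genes of ABA catabolism rose, with ABA8ox1 at 3.29 and 11.7 FPKM, ABA8ox2 at 2.47 and 17.4 FPKM, and ABA8ox3 at 1.87 and 3.67 FPKM in untreated and treated seedlings.

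**Figure D1:**
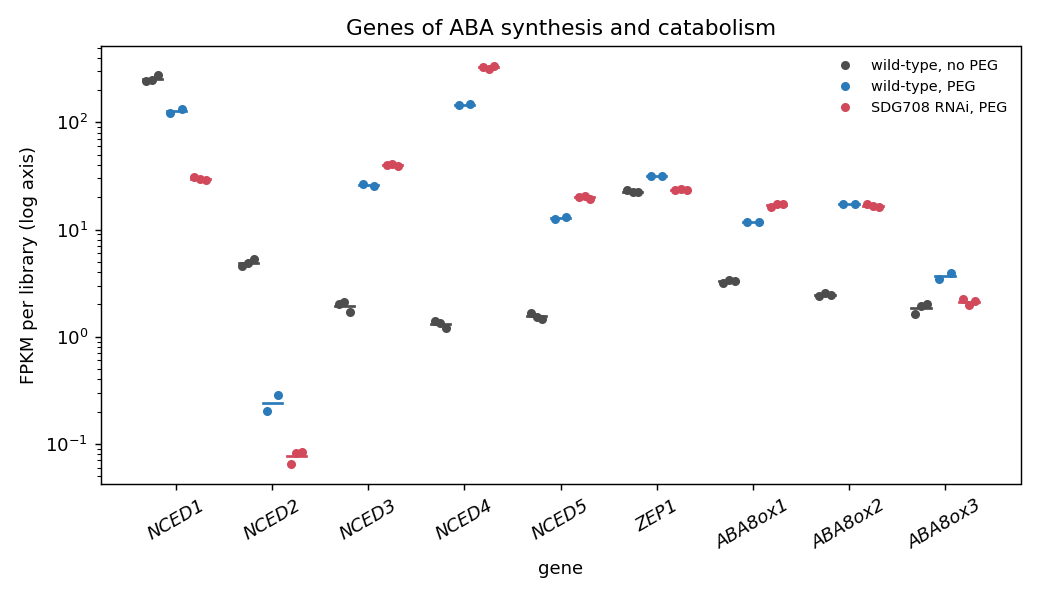
FPKM per library on a log axis for the 9 tested genes of ABA synthesis and catabolism, with a point per library and a line at each group mean. NCED4 lies between 1.2 and 1.41 FPKM in untreated wild-type, between 145 and 148 FPKM in wild-type under PEG and between 313 and 337 FPKM in the RNAi line under PEG, while NCED1 falls from 244 to 277 FPKM through 124 to 132 FPKM to 28.8 to 31 FPKM.

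Clade A protein phosphatases PP2C, which hold ABA signalling in check, rose in 9 of 9 genes (camera adjusted p = 5.1e-06, and adjusted p = 0.13 with an estimated correlation). PP2C30 rose 33.2-fold to 151 ± 6.74 FPKM (SD, n = 2), PP2C68 25.3-fold to 241 ± 20.2 FPKM, PP2C49 17.5-fold to 163 ± 18.1 FPKM and PP2C50 6.61-fold to 59.1 ± 0.741 FPKM. Among the SnRK2 kinases, some of which these phosphatases inhibit, 7 of 10 rose and 2 fell, and the list did not pass (adjusted p = 0.065). SAPK6 rose 4.07-fold and SAPK1 3.14-fold, and SAPK7 fell to 0.741 of its untreated level. Without WT_control replicate 2 or 3, either WT_PEG replicate or RNAi replicate 1, 1 SnRK2 gene fell, while 3 fell with equal medians (7 rising) and with quantile normalization, limma-voom or total recovered reads (6 rising). Stress transcription factors rose in 13 of 15 tested genes and fell in 0 (adjusted p = 1.4e-05, and adjusted p = 0.23 with an estimated correlation). SNAC1 went from 19.4 ± 0.728 to 350 ± 12.2 FPKM, DREB1C from 0.67 ± 0.0422 to 19.2 ± 1.8 FPKM, NAC10 from 5.51 to 56.9 FPKM and bZIP23 from 7.59 to 60.5 FPKM. With libraries scaled to equal medians or to total reads, or without WT_control replicate 2, 12 rose and 1 fell. In osmolyte metabolism 6 of 8 tested genes rose and 1 fell (adjusted p = 0.015, and adjusted p = 0.13 with an estimated correlation). The galactinol synthase genes GOLS2 and GOLS1 rose 20.7-fold and 16.8-fold and the ornithine aminotransferase gene OAT 3.76-fold, while TPS1 fell to 0.587 of its untreated level. With equal medians, quantile normalization, limma-voom or total recovered reads, and without RNAi replicate 2, 2 osmolyte genes fell.

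Leaf photosynthesis genes fell in 9 of 12 cases under PEG (camera adjusted p = 0.0046, and adjusted p = 0.51 with an estimated correlation). RBCS2, a Rubisco small subunit gene, fell from 6643 ± 564 FPKM (SD, n = 3) to 2282 ± 83.8 FPKM (SD, n = 2), and LHCB5 from 1373 ± 105 to 586 ± 27.1 FPKM. Copies of RBCS are nearly identical, and their separate values are uncertain. The 3 tested root-preferential genes fell further. The silicon transporter genes LSI1 (LOC_Os02g51110) and LSI2 (LOC_Os03g01700) fell to 0.108 and 0.0958 of their untreated levels, and RCC3 (LOC_Os02g44310) to 0.161. Aquaporins went both ways, with 7 of 13 higher and 5 lower (adjusted p = 0.92, with a median log2 fold change of 0.4 and a mean of -0.08). TIP1-2 rose 3.78-fold, while TIP2-1 fell to 0.308, PIP2-5 to 0.256, PIP2-3 to 0.35 and PIP2-4 to 0.371. Quantile normalization left 3 aquaporin genes higher and 6 lower. Among antioxidant enzyme genes 4 of 6 rose and 2 fell (adjusted p = 0.72), with the catalase gene CATA at 486 ± 19.6 and 183 ± 0.957 FPKM and the superoxide dismutase gene SODCC2 at 29.2 ± 1.84 and 49.6 ± 0.798 FPKM. Of 8 circadian clock genes 4 rose and 2 fell (adjusted p = 0.72). GI rose 1.85-fold and PRR1 fell to 0.588. The clock counts were 2 higher and 3 lower with limma-voom on recovered reads or scaling to total recovered reads, 2 higher and 2 lower with quantile normalization, and 4 higher and 1 lower without WT_PEG replicate 2. Among lists too short for a test, flowering time had 2 genes higher and 1 lower of 3, with HD1 rising from 0.204 to 2.06 FPKM, and jasmonate synthesis had 1 higher (AOS2, 1.94-fold) and 1 lower (AOC, to 0.835) of 3. The histone methyltransferase genes SDG725 (2.27 and 2.66 FPKM) and SDG724 (2.33 and 2.36 FPKM) did not pass, although SDG725 did without WT_control replicate 2 (limma adjusted p = 0.043). Counts adjusted over the list alone equalled those over all genes in every list of this comparison.

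Across all genes 15778 of 20943 differed, 8076 higher and 7702 lower under PEG (limma with Benjamini-Hochberg adjustment). At least 2-fold changes on the log2(FPKM + 1) scale numbered 2188 higher and 1677 lower. The locus LOC_Os02g43330, which has no name in the tables, rose from 2.54 to 856 FPKM and LOC_Os11g07911 from 0.614 to 330 FPKM, while LOC_Os10g05950 fell from 37.6 to 0.206 FPKM and LOC_Os02g13660 from 35.3 to 0.553 FPKM. Scaling to total recovered reads gave 6533 higher and 9195 lower. It moved the median log2 fold change of all genes from 0.02 to -0.09, so the balance of small rises and falls depends on the scaling.

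The second comparison asked which transcripts differed between the SDG708 RNAi line and wild-type, both under PEG. In ABA synthesis 3 of 6 tested genes were higher and 3 lower in the RNAi line. NCED1 was at 29.9 ± 1.09 FPKM (SD, n = 3) against 128 ± 6.18 FPKM (SD, n = 2), a log2 fold change of -2.06 ± 0.07 (SE, limma adjusted p = 9.8e-08). ZEP1 was at 23.5 ± 0.19 against 31.6 ± 0.408 FPKM, and untreated wild-type had 22.7 ± 0.442 FPKM. NCED2 was at 0.0768 ± 0.0101 against 0.243 ± 0.0602 FPKM, and its call (limma adjusted p = 0.037) was lost without a filter on low values and without WT_control replicate 2, either WT_PEG replicate or any RNAi replicate (highest limma adjusted p = 0.21). NCED4, NCED3 and NCED5 were higher in the RNAi line, at 326 ± 12, 40.2 ± 1.03 and 19.9 ± 0.471 FPKM against 146 ± 2.11, 26 ± 0.832 and 12.9 ± 0.471 FPKM. The list did not pass camera (adjusted p = 0.92, with a median log2 fold change of 0.2 and a mean of -0.05). In ABA catabolism ABA8ox1 was higher by 1.44-fold, ABA8ox3 was lower at 0.578 of wild-type, and ABA8ox2 had 16.7 and 17.4 FPKM in RNAi and wild-type seedlings.

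Stress transcription factor genes were higher in the RNAi line in 9 of 15 tested cases and lower in 1 (camera adjusted p = 0.00074, and adjusted p = 0.55 with an estimated correlation). DREB1C was at 51.9 ± 6.08 against 19.2 ± 1.8 FPKM, NAC5 at 119 ± 4.92 against 59.7 ± 0.169 FPKM, SNAC1 at 665 ± 12 against 350 ± 12.2 FPKM, NAC10 at 93.3 ± 3.04 against 56.9 ± 1.13 FPKM and NAC6 at 528 ± 19 against 330 ± 6.02 FPKM. LEA and dehydrin genes were higher in 6 of 10 cases and lower in 1 (adjusted p = 0.062). LIP9 was at 1809 ± 122 against 1115 ± 6.13 FPKM and RAB16C at 243 ± 9.77 against 168 ± 5.74 FPKM, EM and WSI18 were higher by 1.4-fold and 1.26-fold, and RAB16D was lower at 17.2 ± 0.277 against 22.2 ± 0.116 FPKM. Beside these groups, transcripts of seed storage proteins, a list chosen after its values were seen, were higher in the RNAi libraries, with 1942 to 3274 reads per library against 142 to 240 in the wild-type libraries. Clade A PP2C genes were higher in 3 of 9 cases (adjusted p = 0.27), with PP2C30 at 200 ± 6.95 against 151 ± 6.74 FPKM, PP2C68 at 307 ± 18.5 against 241 ± 20.2 FPKM, and PP2C50 and PP2C06 at 56.9 and 57 against 59.1 and 55 FPKM. The call of PP2C68 (limma adjusted p = 0.018) was lost without WT_PEG replicate 1, RNAi replicate 1 or RNAi replicate 3 (highest limma adjusted p = 0.14) and with quantile normalization (limma adjusted p = 0.15, with a log2 fold change of 0.14), which turned the PP2C counts to 2 higher and 2 lower. SnRK2 kinases were higher in 5 of 10 cases and lower in 1 (adjusted p = 0.17), led by SAPK2 at 22.5 ± 0.923 against 12.1 ± 0.153 FPKM, with SAPK6 higher by 1.31-fold, SAPK9 by 1.52-fold and SAPK1 by 1.18-fold, and without either WT_PEG replicate 0 were lower. There were 2 lower without WT_control replicate 3, with equal medians, limma-voom or total recovered reads, and 3 with quantile normalization. In osmolyte metabolism 3 of 8 genes were higher and 0 lower (adjusted p = 0.17). GOLS2 and PRODH were higher by 1.35-fold and 1.38-fold, and 5 genes were higher without WT_control replicate 3. OAT was higher by 1.14-fold (limma adjusted p = 0.025). Its call was lost with quantile normalization, limma-voom or total recovered reads, and without RNAi replicate 1 or 2 (highest limma adjusted p = 0.17). Without WT_PEG replicate 2 the call of OAT was lost too, with a log2 fold change of 0.12.

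Leaf photosynthesis genes were lower in the RNAi line in 8 of 12 cases and higher in 0 (camera adjusted p = 0.00074, and adjusted p = 0.55 with an estimated correlation). LHCB3 was at 972 ± 25.9 against 1540 ± 66.1 FPKM, LHCB5 at 395 ± 8.38 against 586 ± 27.1 FPKM, LHCA3 at 935 ± 21.1 against 1395 ± 71.1 FPKM and LHCB4 at 741 ± 17.5 against 1176 ± 96.5 FPKM. The Rubisco genes RBCS2, RBCS3 and RBCS4 were at 2357, 188 and 339 FPKM against 2282, 194 and 338 FPKM. Of the root-preferential genes RCC3 was lower at 42 ± 1.8 against 53.6 ± 0.948 FPKM, and LSI1 and LSI2 were at 5.24 and 4.3 against 5.76 and 4.56 FPKM, LSI1 passing without WT_control replicate 3 (limma adjusted p = 0.045) or with scaling to total recovered reads (0.036). Aquaporins were lower in 6 of 13 cases and higher in 2 (adjusted p = 0.18). TIP2-1 was at 0.554, PIP2-4 at 0.701 and TIP1-2 at 0.846 of wild-type, and TIP2-2 was higher by 1.39-fold. The call of TIP1-2 was lost without WT_PEG replicate 2 (limma adjusted p = 0.11), where 3 aquaporin genes were lower and 1 higher. Without WT_control replicate 3 there were 4 higher, and without WT_control replicate 1, WT_PEG replicate 1, RNAi replicate 1 or RNAi replicate 3 there was 1. Limma-voom and scaling to total recovered reads gave 1 higher and 7 lower. Among circadian clock genes 1 of 8 was higher and 3 were lower (adjusted p = 0.18), with PRR37 and PRR73 at 0.732 and 0.835 of wild-type. The gene higher was PRR1, by 1.17-fold, and its call (limma adjusted p = 0.028) was lost without either WT_PEG replicate or RNAi replicate 2, and with limma-voom or scaling to total recovered reads (highest limma adjusted p = 0.18). The call of GI, at 0.891 of wild-type (limma adjusted p = 0.036), was lost with the replicate block (limma adjusted p = 0.054, log2 fold change -0.14). It was also lost without WT_control replicate 1, RNAi replicate 1 or RNAi replicate 3 (highest limma adjusted p = 0.11). Without WT_PEG replicate 1 or 2 the call of GI was lost too, with a log2 fold change of -0.15 or -0.18. Without either WT_PEG replicate the clock counts were 0 higher and 2 lower. Antioxidant enzyme genes were higher in 3 of 6 cases and lower in 1 (adjusted p = 0.27), with SODCC2 higher by 1.83-fold and CATC lower at 0.65, and quantile normalization turned these counts to 1 higher and 3 lower. The flowering gene MADS50 was lower at 0.786 and HD1 higher by 1.38-fold, both calls being lost without WT_PEG replicate 1 (limma adjusted p = 0.07 and 0.057) and that of HD1 also with a pseudocount of 0.1 (limma adjusted p = 0.064). MADS51 passed as higher without WT_control replicate 3 (limma adjusted p = 0.023), with array weights (0.025) and with only the 2 groups compared (0.041). Of 3 jasmonate genes OPR7 was higher by 1.37-fold and AOC by 1.15-fold, the latter call being lost without either WT_PEG replicate or RNAi replicate 1 (highest limma adjusted p = 0.094) and with quantile normalization (limma adjusted p = 0.21), where its log2 fold change was 0.07 in place of 0.2. SDG725 and SDG724 were at 2.49 and 2.31 FPKM against 2.66 and 2.36 FPKM and did not pass. Adjusted over the list alone, the counts changed to 11 higher and 1 lower for stress transcription factors, 6 and 2 for SnRK2 kinases, 3 and 6 for aquaporins, 2 and 1 for flowering time and 9 lower for leaf photosynthesis.

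**Figure D2:**
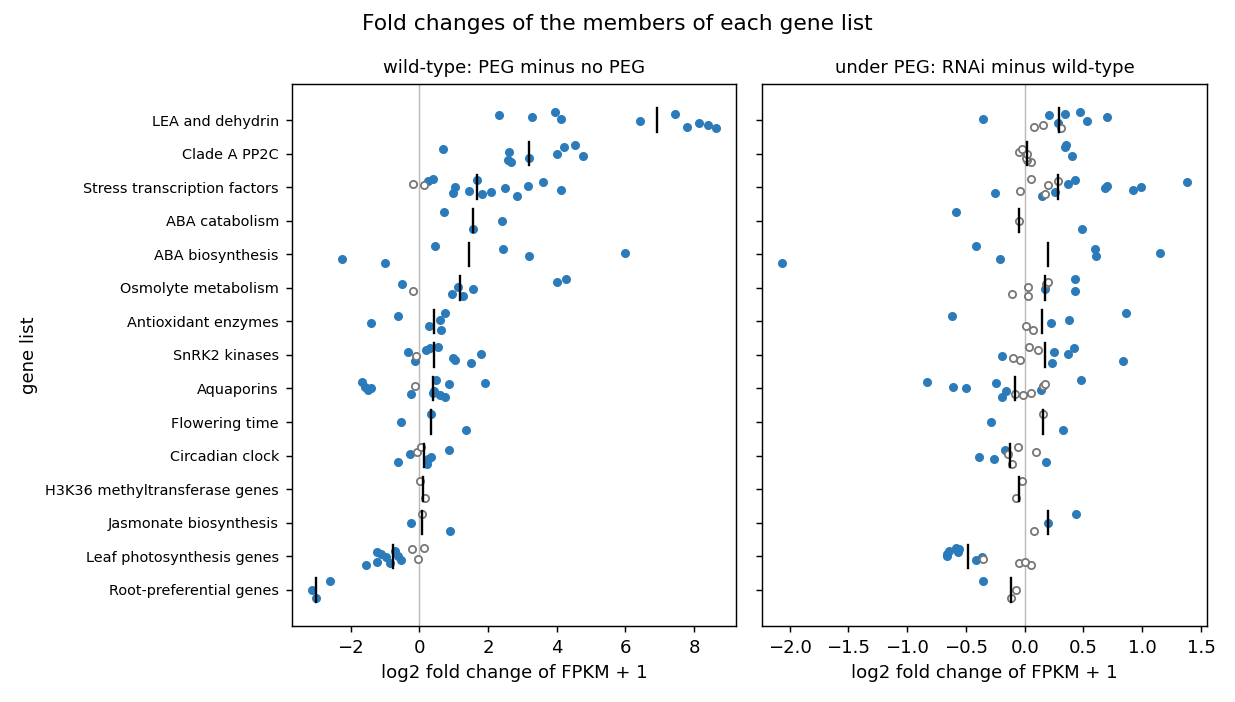
Log2 fold changes of FPKM + 1 for each tested member of the 15 gene lists, in wild-type PEG minus no PEG (left) and in RNAi minus wild-type under PEG (right), with filled points for an adjusted p under 0.05, open points for others, and a bar at the list median. The LEA and dehydrin list has a median of 6.92 on the left and 0.29 on the right, and the leaf photosynthesis list -0.78 and -0.48.

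Across all genes 7879 of 20943 differed between the RNAi line and wild-type under PEG, 4451 higher and 3428 lower (limma with Benjamini-Hochberg adjustment), of which 261 and 124 changed at least 2-fold on the log2(FPKM + 1) scale. Scaling to total recovered reads turned the balance to 3432 higher and 4417 lower, and the count was 5174 without WT_PEG replicate 2. LOC_Os11g40530 was at 97.8 ± 10.2 FPKM in the RNAi line and 0.0775 ± 0.0333 FPKM in wild-type, and LOC_Os07g32710 at 79 ± 6.22 and 0.287 ± 0.0552 FPKM. LOC_Os06g38450 was at 4.85 ± 0.315 against 37.4 ± 0.39 FPKM and LOC_Os02g10780 at 0.899 ± 0.151 against 8.84 ± 0.0524 FPKM.

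The treated RNAi line was also set against untreated wild-type, a comparison in which genotype and treatment both differ. LEA and dehydrin genes were higher in 10 of 10 cases, clade A PP2C genes in 9 of 9 and stress transcription factors in 14 of 15, and leaf photosynthesis genes were lower in 12 of 12. Their camera adjusted p were 1.7e-06, 1.6e-05, 7.2e-06 and 0.00023, and with an estimated correlation the adjusted p were 0.12, 0.12, 0.21 and 0.43. Osmolyte metabolism (7 higher and 1 lower of 8, adjusted p = 0.0071) and SnRK2 kinases (8 higher and 1 lower of 10, adjusted p = 0.012) passed too, with an adjusted p of 0.12 for both with an estimated correlation. In all 16978 of 20943 genes differed, 8592 higher and 8386 lower, and scaling to total recovered reads gave 6706 higher and 10521 lower, with a median log2 fold change of all genes of -0.16 in place of 0.01.

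Genes called in both of the first 2 comparisons numbered 6490, and 4272 of them (65.8%) had the same direction. Higher in both were 2605 genes against 1716 from independent lists, and lower in both 1667 against 1261. Genes higher under PEG and lower in the RNAi line numbered 1042 against 1322, and the reverse 1176 against 1637. The balance of shared rises and falls turned with the scaling, to 1901 higher and 2411 lower in both with total recovered reads, 1965 and 2553 with limma-voom and 1888 and 2084 with quantile normalization, while the same-direction share was 67%, 67.4% and 64.2%. Both comparisons use the WT_PEG libraries with opposite sign, which by itself pushes the fold changes apart. The covariance of the fold changes across genes was 0.065, against a mean of -0.0039 in simulated data without effects, a difference of 0.0689. Their correlation across genes, which are not independent replicates, was 0.2. In the simulated data it was -0.61, set by the shared libraries alone because those data hold no effects. These correlations therefore cannot be compared in size. With a different WT_PEG library in each comparison, a setting chosen after the data were seen in which a lone sample is assumed to vary like the other groups, the covariance was 0.0695 with replicate 1 in the PEG response and 0.068 with replicate 2. The same-direction counts were then 2995 of 4295 (69.7%) and 2810 of 4158 (67.6%), against 50.2% from independent lists in both. Without WT_PEG replicate 2 the same-direction count was 2731 (66.1%).

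**Figure D3:**
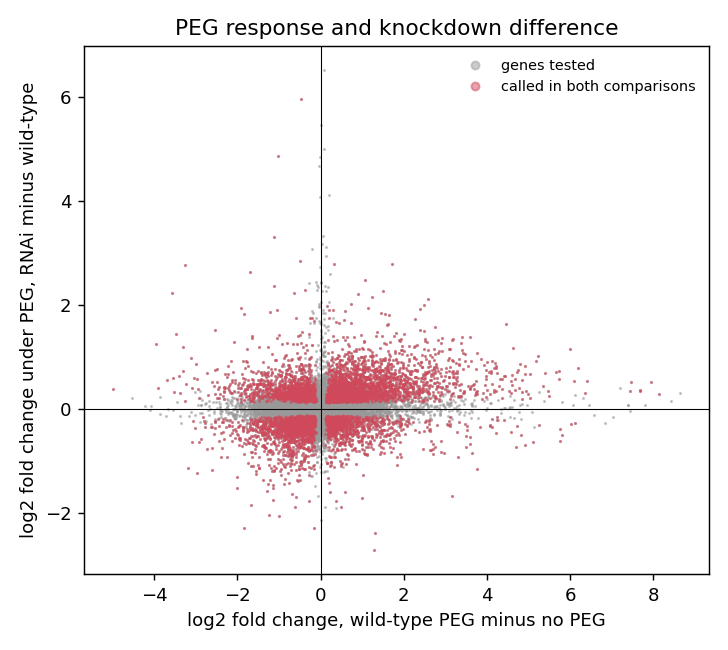
Log2 fold change of each tested gene under PEG in wild-type (horizontal) and in the RNAi line against wild-type under PEG (vertical), with genes called in both comparisons in red. Of the 6490 red points 4272 lie in the upper right and lower left parts of the plot.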

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

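Limma-voom, scaling to total recovered reads, averaging WT_control replicates 1 and 2, and a different WT_PEG library in each comparison were chosen after the data were seen. A stricter filter tested fewer genes and called 8484 for the PEG response, 4867 for the RNAi comparison under PEG and 8947 for the treated RNAi line against untreated wild-type, against 15778, 7879 and 16978. All other planned and added settings with all libraries kept these 3 counts within 1.5 times. With an estimated inter-gene correlation 0 lists passed camera in any of the 3 comparisons, against 5, 2 and 6, while 3, 0 and 4 had an unadjusted p under 0.05, and the cause was not tested. The self-contained test fry, which does not compare a list with other genes, called 7 lists for the RNAi comparison under PEG. Fry also gave the aquaporin list a reversed direction, lower, in the treated RNAi line against untreated wild-type, where the median log2 fold change was 0.28 and the mean -0.21. A threshold of 2-fold in both comparisons left 124 genes with the same direction (80.5%), by construction fewer. With WT_PEG replicate 2 for the PEG response and replicate 1 for the RNAi comparison, by construction fewer libraries, 2810 genes had the same direction, and 2995 the other way round.

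Leaving out 1 library at a time gave 14242 to 16043 genes for the PEG response, 5174 to 9337 for the RNAi comparison under PEG, 16258 to 17169 for the treated RNAi line against untreated wild-type and 2731 to 5037 genes with the same direction in both. Where a WT_PEG library was left out, the lone sample was assumed to vary like the other groups. Without WT_control replicate 3, which stood apart from the others, the first 3 counts were 16043, 9337 and 17169. The authors' deposited p-values under 0.05 numbered 15328 for the PEG response and 8453 for the RNAi comparison, and the 15777 and 7879 called genes with a deposited p-value had the same sign in the authors' deposited table.

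With the replicate block the 3 counts were 15849, 7714 and 17213 and the same-direction count 4246, and the block kept the number of lists at 5, 2 and 6. Whether the replicate numbers pair the samples was not settled. Deviations of same-numbered libraries from their group means correlated across genes at 0.25 and -0.23 between WT_control and WT_PEG, at -0.12, 0.36 and 0.29 between WT_control and 708RNAi_PEG, and at -0.09 and -0.21 between WT_PEG and 708RNAi_PEG. Differently numbered WT_control and 708RNAi_PEG libraries gave -0.4 to 0.23. The deviations of the 2 WT_PEG libraries are exact opposites, so values with them cannot show pairing or its absence.

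Of 2628 values for 126 named-gene results under the alternatives, 2572 kept their side of the threshold, 42 lost a call, 12 gained one and 2 reversed. Called genes among the 2572 also kept their direction, while a change of sign in a gene not called in either fit was not counted. The reversals came with quantile normalization in the PEG response, where OPR7 had a log2 fold change of -0.16 and PRR73 of -0.01, and the cause was not tested. SDG708 was not analysed here, so the alternatives for it were not run, and the third comparison has no deposited p-values among the columns used here. Simulated data had these depths and numbers of libraries, a 5% variation beyond counting and 200 changed genes per draw. There 1.2-fold changes were called in 15% of cases for the PEG response and 2-fold changes in 99%. Far more genes were called in the real data, so these shares do not carry over to it. Depth was not varied, so its own part was not tested.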

Other observations

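Every test in this part was chosen after the result was seen, except the count of other splits of the samples. In all, 38 loci had at least 1 FPKM in every RNAi library and over 16 times the level of every wild-type library, and 0 showed the reverse. The same rule found 237 genes on and 22 off under PEG, comparing all treated with all untreated libraries. Of the 38 loci 3 belong to a list of 11 storage protein genes of the rice grain (PROLM25, GLUB2 and GLUB5), and no enrichment was tested. The prolamin gene PROLM25 was at 20.6 ± 1.81 FPKM (SD, n = 3) against 0.271 ± 0.325 FPKM (SD, n = 2) in wild-type under PEG, the albumin gene RAG2 at 14.1 ± 1.02 against 1.54 ± 0.527 FPKM, RA5 at 8.56 ± 0.579 against 0.447 ± 0.0734 FPKM and the glutelin gene GLUA1 at 5.59 ± 0.298 against 0.304 ± 0.209 FPKM. RAG2, RA5 and GLUA1 did not meet the 16-fold rule. These genes were picked after their values were seen.

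For the storage proteins, 11 of the 11 listed genes were higher in every RNAi library than in every wild-type library, which chance gives in 1.8% of cases for a single gene, a share that says nothing here because the list was chosen after its values were seen. Reads shared between copies of one family are argued against as the whole cause, because genes of 3 families (glutelins, albumins and prolamins) were higher. RNA from seed tissue in the RNAi libraries may be a source of all 11, and it cannot be told apart from an effect of the RNAi line, because all RNAi libraries form 1 group, while the wild-type libraries also held 142 to 240 reads of these genes each. The starch synthase gene WX of the endosperm had 0.119 ± 0.0297 FPKM (SD, n = 3) in the RNAi line and 0.127 ± 0.0137 FPKM (SD, n = 2) in wild-type under PEG, but its level in such tissue is not known here. An effect of the genotype stays open and was not tested.

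Of the genes called in both comparisons, 65.8% had the same direction in the RNAi comparison as in the wild-type PEG response, although the median RNAi log2 difference was 0.07 in genes that rose under PEG and -0.02 both in genes that fell and in genes not called, so that the shift in medians lay in the genes that rose. The shared WT_PEG libraries are argued against, since the covariance of 0.065 lay above the highest of 100 simulated values (-0.0035) and was 0.0695 and 0.068 with a different WT_PEG library in each comparison. One scaling factor per library is argued against as the whole cause. Such a factor moves all genes the same way, although low genes less on the log2(FPKM + 1) scale. The median RNAi difference was 0.1 higher in genes that rose under PEG than in genes that fell, and those medians had opposite signs. It was 0.09 to 0.11 with any library left out, which does not vary the scaling. With total recovered reads, limma-voom and quantile normalization the same-direction share was 67%, 67.4% and 64.2%. A stronger dehydration of the RNAi plants through handling could give the slope of 0.074 of RNAi on PEG fold changes and cannot be told apart from an effect of the genotype, because all RNAi libraries form 1 group. The genotype itself stays open as an untested explanation.

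Root-preferential genes fell under PEG in wild-type. A smaller share of root tissue may contribute, since even RCC3, the least changed, had a log2 ratio of -2.64, and it cannot be told apart from a response of these genes, because the labels, which give seedling as the tissue, do not record the share of roots. The log2 ratio of RCC3 lay 0.74 ± 0.17 (SE) above that of LSI2, which decides nothing, because the levels of these genes outside roots are not known here. A response of these genes to PEG stays open and was not tested.

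For the treated RNAi line against untreated wild-type, the real split of the 6 libraries called 16978 genes and the highest of the other splits 0 (limma; at an unadjusted p under 0.05 the highest was 459), so that 1 of the 10 splits gave as many. With 10 splits no share under 0.05 can be reached. The other splits also mix libraries of both groups, so the difference between the groups enters the spread. Low counts were therefore due in advance and decide nothing.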
